A study of Mus musculus with 9 samples.

How the data were processed

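Cells of mouse embryonic forelimbs that carried the Scx-GFP reporter, in which green fluorescent protein follows the tendon gene Scx, were profiled at embryonic days 11.5, 12.5 and 14.5 (E11.5, E12.5 and E14.5). Per the labels, the forelimbs were dissociated with trypsin, GFP-positive cells were collected on either of 2 cell sorters, and amplified total RNA was hybridized to Affymetrix mouse expression arrays, which hold short probes for each transcript. Which sorter was used for which sample is not given. Each stage has 3 arrays, named A, B and C in the labels. The labels do not say whether the 3 samples of a stage came from separate litters, so every p-value measures the spread between these samples and no more.

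The deposited values are one intensity per probe set and array, the signal computed by the authors with MAS5 in Affymetrix Expression Console 1.1, per the submitters' processing notes. They lie on a linear scale between 0.0409 and 45906.5. The mean of each array's signals, leaving out the lowest and highest 2% of them, was 500, so the arrays had been scaled to a common mean, and they were used with no further normalization. Median signals ranged from 68.7 to 118 over the 9 arrays. No pair of arrays held the same values. The number of arrays limits the precision.

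Of 45101 probe sets, 64 were control probe sets, 34945 were listed with 1 gene symbol, 932 with several symbols and 9160 were not in the list of genes. Those with 1 symbol were used, and each of 18193 genes was represented by the probe set with the highest mean log2 signal over the 9 arrays, chosen without regard to stage. Probe sets with the suffix _x_at, which can bind related sequences, were taken only where a gene had no other. Gene symbols were checked through their gene identifiers against the RefSeq table of mouse genes. Signals below 22.7, the 25th percentile of all signals, were set to that floor before log2 transformation. A gene was tested if its signal exceeded 90.6, the median of all signals, in at least 3 of the 9 arrays, which left 11575 genes. Signals are given as means with the SD over 3 arrays, before the floor was applied. Changes are given as log2 values with their standard error (SE).

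The 3 stages were compared with limma 3.58.1 in R 4.3.3, in one fit of all 9 arrays with 1 mean per stage (6 residual degrees of freedom). Each pair of stages was a two-sided contrast with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. limma's F-test asked for any difference among the stages. Where a gene was at the floor in all arrays of a stage, its change is measured from that floor and depends on it. A further 28 gene lists of 540 genes were written by hand, of which 501 had a probe set and 438 were tested. They cover tendon matrix and regulators, signalling, patterning, cell state and markers of other cell types. Lists with at least 5 tested members (26 lists, 78 list and contrast pairs) were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment within each contrast. Camera was also run with a correlation estimated for each list, and the rotation test fry was run on the same lists. Fry asks whether a list's members changed in one direction, without comparing them with other genes. A fry call without a camera call therefore shows no shift beyond that of other genes. A list is called by camera at its preset correlation unless another test is named. For lists in the text the fry value is given where its outcome differs. At the preset correlation camera also called lists in groups of arrays that mix the stages, as given near the end.

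Named genes were fixed by a rule. In each contrast it takes the 6 largest rises and the 6 largest falls among called genes whose arrays do not overlap between the stages, up to 4 called members with the largest change from each list, and Scx, Mkx, Egr1, Tnmd, Col1a1, Col1a2, Sox9 and Myog whether called or not. A subset is printed, from the top of each ranking. A few genes outside the rule are named and are said to have been chosen after their values were seen. The lists, the rule, the filter, the tests and the alternatives were fixed before the data were examined, except where stated.

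The array letters were checked as possible pairs. After the mean of each stage was removed, the deviations of arrays with the same letter were correlated across genes. Between E11.5 and E14.5, r was 0.313, -0.00516 and 0.238 for letters A, B and C. It was 0.520, 0.133 and 0.332 between E11.5 and E12.5, and 0.310, 0.121 and 0.289 between E12.5 and E14.5. In the comparisons with E12.5, each array of the later stage had its highest r with the same letter of the earlier stage. Between E11.5 and E14.5 this held for letters A and C but not for B. The labels do not say what a letter stands for, so the arrays were treated as unpaired. A fit with the letters as a replicate block was run as an alternative, and its value is given where it changes a call.

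Other alternatives were no floor, a pseudocount in its place, a higher floor at the median of all signals, no filter, a stricter filter at the 65th percentile of signals, quantile normalization, median centring, the mean of a gene's probe sets, every probe set tested alone, limma with a trended and robust prior, array weights, the ratio of 3' to 5' control signals as a covariate, fits of only the 6 arrays of a contrast, a minimum change of 2-fold, each array left out in turn, and all arrays of letter A left out. Counts were compared with those of the other splits of the same arrays. The method was tested on simulated data for 11575 genes with the spread measured for each gene and known changes added between E14.5 and E11.5. At 1.5-, 2-, 4- and 8-fold it recovered 22%, 54%, 94% and 98% of 50 changed genes each, and 5 of its 139 calls (3.60%) were unchanged genes. Far fewer genes were changed there than the 4691 called between E14.5 and E11.5 in the data. The Benjamini-Hochberg threshold depends on how many genes change, so these shares do not carry over to the data. A list whose members were all raised 2-fold at E14.5 passed an unadjusted p under 0.05 in camera in 50 of 50 draws, and one that was not moved in 2 of 50. The simulated genes varied independently of each other, so these list numbers do not hold for lists whose genes are correlated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.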

Results

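Gene expression was measured in sorted Scx-GFP-positive forelimb cells from mouse embryos at E11.5, E12.5 and E14.5, on 3 arrays per stage and 9 in all. Scx encodes scleraxis, a transcription factor of tendon and ligament progenitors, so the series follows reporter-positive cells of the limb across days in which limb tendons form. The arrays had median signals of 68.7, 79.6 and 106 at E11.5, of 69.5, 94.5 and 106 at E12.5, and of 81.5, 91.1 and 118 at E14.5, each in the order A, B, C. Between 0.121% and 1.32% of the tested genes lay at the floor of signal in an array. Arrays of the same stage correlated with r between 0.950 and 0.982 across genes, which are not independent replicates. E11.5 correlated with E12.5 arrays between 0.953 and 0.976, a range that overlaps the one within stages, E12.5 with E14.5 arrays between 0.891 and 0.940, and E11.5 with E14.5 arrays between 0.830 and 0.889. E11.5 A correlated more with E12.5 A (0.976) than with E11.5 B (0.969) or E11.5 C (0.975). The first principal component held 65.3% of the variance and ran from -49.0 to -38.1 in the E11.5 arrays, from -17.9 to -8.35 in the E12.5 arrays and from 49.9 to 65.8 in the E14.5 arrays. On the second component, which held 11.1%, the 3 arrays of letter A lay at 20.6, 23.8 and 25.8 and all others between -25.0 and -4.78.

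**Figure D1:**
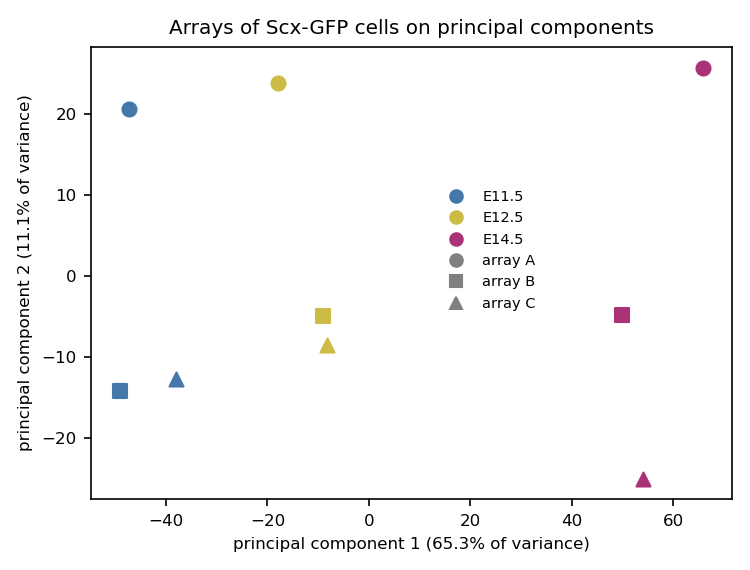
Principal components of the log2 signals of the tested genes, with component 1 on the horizontal axis and component 2 on the vertical axis, 1 point per array, coloured by stage and marked with its letter. The stages separate along component 1, and the arrays of letter A lie at 20.6 to 25.8 on component 2.

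E14.5 was compared with E11.5 to find how the sorted cells differed between the ends of the time course. Tnmd, which encodes tenomodulin, a membrane protein of differentiated tenocytes, had a mean signal of 21.4 ± 18.1 (SD, n = 3) at E11.5, with 2 of 3 arrays at the floor, and of 8066 ± 1811 at E14.5 (log2 8.15 ± 0.55, adjusted p = 7.1e-06). Aspn, which encodes the small leucine-rich proteoglycan asporin, was at the floor in all E11.5 arrays and reached 4242 ± 736 at E14.5, a log2 rise of 7.53 ± 0.32 from that floor (adjusted p = 9.6e-07). The other largest rises were those of Chodl, which encodes the membrane protein chondrolectin (log2 6.81 ± 0.38), Slc26a7, which encodes an anion transporter (6.43 ± 0.41), Dpt, which encodes the matrix protein dermatopontin (6.34 ± 0.28), and Ecrg4 (6.18 ± 0.47). The largest fall was that of Shh, the signal of the posterior limb bud margin, from 1019 ± 193 to 26.4 ± 6.04 (log2 -5.22 ± 0.35, adjusted p = 6.7e-06). Igdcc3 (-4.55 ± 0.32), the DNA-binding protein gene Arid3b (-4.43 ± 0.21), the zinc finger gene Zic5 (-4.00 ± 0.32), Trim71 (-3.88 ± 0.18) and the limb bud transcription factor gene Sall4 (-3.79 ± 0.28) followed. The order of these falls depends on the floor: with the higher floor Igdcc3 changed by -4.42, Zic5 by -3.48, Shh by -3.47, Trim71 by -3.45, Sall4 by -2.65 and Arid3b by -2.45. The 6 rises were then between 4.53 (Dpt) and 6.45 (Tnmd), and all of these calls held. With no floor Tnmd rose by 8.88, Aspn by 8.80, Chodl by 7.73, Dpt by 7.35 and Ecrg4 by 7.07, and Arid3b fell by 5.89. With the mean of probe sets Ecrg4 changed by 5.42 and Igdcc3 by -3.83, and the change of Sall4 was also smaller.

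Among the tendon transcription factors, Mkx, which encodes Mohawk, a regulator of tendon collagen genes, rose from 429 ± 73.4 to 1731 ± 311 (log2 2.01 ± 0.19, adjusted p = 5.7e-05). Scx itself fell from 19338 ± 3927 to 11152 ± 3339 (-0.81 ± 0.22, adjusted p = 0.0164), with E14.5 C (14952.5) above E11.5 A (14810.7). The cells were sorted on the Scx reporter, so this fall cannot be told apart from a difference in which cells the sort kept. Egr1, a zinc finger gene active in tendon and also an immediate early gene, rose from 6169 ± 7922 to 20525 ± 4069 (2.64 ± 0.83, adjusted p = 0.0300), and the immediate early genes Atf3, Fosb and Klf4 rose too. Of 7 tested members of this list 3 rose and 1 fell, and the same numbers were called adjusted over the list alone. The third that rose was Eya2, a call lost with the letters as a block. The list as a whole was not called by camera (median log2 change 0.97, adjusted p = 0.340) but was by fry (0.0072). The call of Scx was lost without E11.5 B, E11.5 C, E14.5 A or E14.5 B (highest adjusted p 0.0589). That of Egr1 was lost without E11.5 B, E11.5 C or any 1 of the E14.5 arrays (highest 0.0969), with no filter (0.101) and with a trended and robust prior (0.0800). Its log2 change was 3.62 without the letter A arrays, 3.76 without E11.5 A and 1.80 without E11.5 B.

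All 11 tested tendon collagen genes rose, and as many adjusted over the list alone. Col1a1, which encodes a chain of the main fibrillar collagen of tendon, rose from 1125 ± 177 to 11983 ± 2278 (log2 3.41 ± 0.18, adjusted p = 1.9e-06), and Col14a1, which encodes a fibril-associated collagen, from 141 ± 49.0 to 4898 ± 891 (5.16 ± 0.26). The collagen VI genes Col6a1 (4.20 ± 0.22) and Col6a3 (3.92 ± 0.23) followed. Col1a2, the other type I collagen gene, rose from 17133 ± 2599 to 31816 ± 5113 (0.89 ± 0.17, adjusted p = 0.0031), a call lost after median centring of the arrays. All 21 tendon proteoglycan and matricellular genes rose, and as many adjusted over the list alone, among them Postn (5.57 ± 0.56, and 6.24 without E11.5 B), which encodes periostin, and Ogn (5.34 ± 0.28), which encodes osteoglycin. Of 20 genes of collagen processing and crosslinking 17 rose, 19 adjusted over the list alone, led by the lysyl oxidase gene Lox (4.37 ± 0.21) and the prolyl hydroxylase gene P4ha3 (2.76 ± 0.18). Of 11 elastic fibre and microfibril genes 10 rose, and as many adjusted over the list alone, led by Mfap5 (4.32 ± 0.32), Fbln5 (3.54 ± 0.21) and the elastin gene Eln (3.52 ± 0.27). In camera, which compares a list with all other genes, the collagens (median log2 change 2.80) had an adjusted p = 1.9e-09, the proteoglycans (3.68) 2.6e-13, the processing genes (1.07) 4.9e-08 and the elastic fibre genes (1.22) 6.3e-06. Adjusted p = 0.117 with an estimated correlation for the collagens and for the proteoglycans, 0.206 for processing and 0.145 for elastic fibres. Mfap5 changed by 3.29 with the higher floor.

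**Figure D2:**
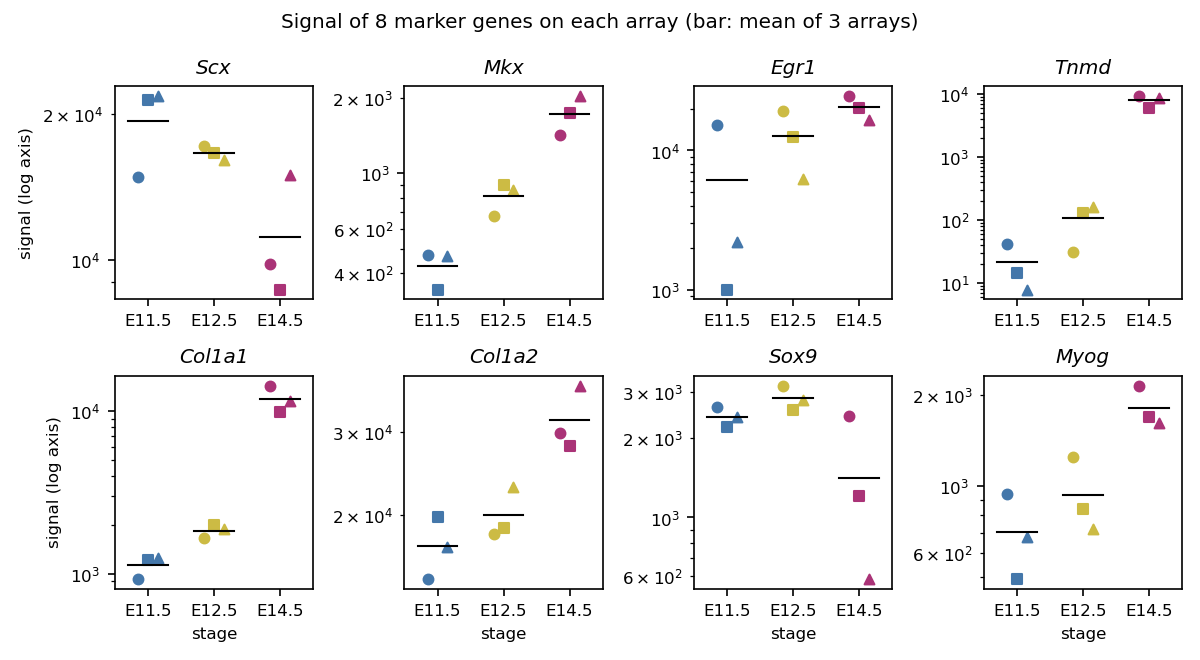
Signal of 8 marker genes per array, on a log axis, against stage, with 1 point per array and a bar at the mean of 3. Tnmd goes from a mean of 21.4 at E11.5 to 8066 at E14.5, while Scx goes from 19338 to 11152.

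Signalling genes moved in both directions. Of 27 tested TGF-beta signalling genes 15 rose and 3 fell, and the same adjusted over the list alone. Those that rose included the latent TGF-beta binding protein genes Ltbp2 (log2 3.81 ± 0.48) and Ltbp3 (from 1002 ± 106 to 8077 ± 1575), the inhibin subunit gene Inhbb (2.99 ± 0.41) and the type II receptor gene Tgfbr2 (2.78 ± 0.14, from 839 ± 67.5 to 5763 ± 269). The 3 that fell, Acvr2b (-2.30), Tgif1 (-1.09) and Tgfbr1 (-0.77), lie outside the rule for named genes and were chosen after their values were seen, as was each further gene named for going against its list. Of 32 Wnt signalling genes 13 rose, led by Wnt4 (3.71 ± 0.40), Wnt2 (3.31 ± 0.23) and the secreted Wnt modulator genes Dkk3 (3.14 ± 0.30) and Dkk2 (2.78 ± 0.20), and 2 fell, Frzb (-2.34) and Lef1 (-0.90), with the same numbers adjusted over the list alone. Of 11 genes of the IGF axis 6 rose and none fell, and as many adjusted over the list alone, with Igfbp7 (4.59 ± 0.40), Igfbp6 (2.80 ± 0.49), Igfbp3 (2.08 ± 0.17) and Igf1 (1.80 ± 0.13) first. Of 24 semaphorins, ephrins and other guidance cues 12 rose, led by Sema3e (3.11 ± 0.28) and Sema3c (2.55 ± 0.18), and 2 fell, Nrp2 (-0.61) and Efna2 (-0.53), with the same numbers adjusted over the list alone. Camera called the TGF-beta (median 1.13, adjusted p = 0.0022), Wnt (0.37, 0.0105), IGF (1.04, 0.0017) and guidance lists (0.44, 0.0201). Adjusted p = 0.249 with an estimated correlation for TGF-beta, 0.117 for Wnt, 0.117 for IGF and 0.381 for guidance cues. Lef1 was lost without E11.5 A, E11.5 B or E14.5 C (highest adjusted p 0.0593) and Efna2 without E11.5 A or E14.5 C (0.0741). Without the letter A arrays Lef1 (0.121), Nrp2 (0.0823) and Efna2 (0.106) were lost, as were Nrp2 (0.0736) and Efna2 (0.125) after median centring and Lef1 with array weights (0.0505). The guidance call was lost without E11.5 A (adjusted p = 0.0524) or E14.5 C (0.0524). The FGF and ERK list (5 rose and 2 fell of 20, adjusted p = 0.681), the BMP and GDF list (5 rose and 3 fell of 23, 0.675) and the retinoid list (6 rose and 3 fell of 14, 0.521) were not called by camera, each with the same numbers adjusted over the list alone. Fry called the FGF and ERK (adjusted p = 0.0318) and retinoid lists (0.0177) and not the BMP and GDF list (0.139). Their members with the largest changes were Fgf7 (2.70 ± 0.24), Bmp6 (2.47 ± 0.34), at the floor in all E11.5 arrays, and Aldh1a3 (3.59 ± 0.23), a retinoic acid synthesis gene, while the ERK phosphatase gene Dusp6 (-1.67 ± 0.27) and the retinoic acid degradation gene Cyp26b1 (-1.50 ± 0.14) fell. With the higher floor the change of Bmp6 was 0.50 and was not called (adjusted p = 0.111). The changes were then also smaller, though called, for Wnt4 (2.79), Ltbp2 (2.21), Inhbb (2.10), Wnt2 (1.83), Sema3e (1.72), Aldh1a3 (1.69) and Igfbp6 (1.52). With no floor they were 5.16 for Aldh1a3, 4.32 for Sema3e and 3.16 for Bmp6. With the mean of probe sets Inhbb changed by 1.84 and Wnt4 by 3.06, and without the letter A arrays Ltbp2 by 3.07 and Igfbp7 by 3.94.

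Genes of early limb patterning and of proliferation were lower at E14.5. Of 33 limb patterning transcription factor genes 19 fell, led by Sall4, Sall3 (log2 -2.62 ± 0.34), Meis2 (-2.16 ± 0.35) and Lhx9 (-2.12 ± 0.28), and 2 rose, with the same numbers adjusted over the list alone. The 2 were Twist2 (0.74) and Gli1 (0.59), both chosen after their values were seen. Gli1 was lost without E11.5 A, E11.5 C, E12.5 B, E14.5 A or E14.5 B (highest adjusted p 0.122). After median centring and without the letter A arrays both were lost (Twist2 0.292 and 0.0565, Gli1 0.451 and 0.140), and Gli1 also with no filter (0.0743), after quantile normalization (0.0510) and in a fit of the 6 arrays (0.0694). Sall4 changed by -2.65 with the higher floor and Sall3 by -1.23, less than Meis2 (-2.16) and Lhx9 (-2.12). With no floor Sall3 changed by -3.75. All 7 tested heterochronic genes of the Lin28 and let-7 pathway, which times developmental transitions, fell, and as many adjusted over the list alone: after Trim71, Mycn fell by 2.20 ± 0.23 on the log2 scale, and Igf2bp1 (-1.75 ± 0.17) and Hmga2 (-1.75 ± 0.17) followed. Of 32 cell cycle genes 28 fell, 30 adjusted over the list alone, and none rose. The mitotic kinase gene Aurka (-1.63 ± 0.21), the ribonucleotide reductase gene Rrm2 (-1.56 ± 0.15) and the checkpoint gene Bub1 (-1.56 ± 0.18) fell most. Camera called the patterning (median -0.68, adjusted p = 4.2e-06), heterochronic (-1.75, 4.4e-06) and cell cycle lists (-0.97, 4.8e-12). Adjusted p = 0.117 with an estimated correlation for patterning and for heterochronic genes, and 0.244 for the cell cycle. Of 15 glycolysis genes 3 rose and 5 fell, 3 and 6 adjusted over the list alone, and the list was not called by camera (median -0.05, adjusted p = 0.429) or fry (0.467). The glucose transporter gene Slc2a3 rose (1.18 ± 0.15) and the lactate dehydrogenase gene Ldhb fell (-1.11 ± 0.16).

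Immediate early and heat shock genes were higher at E14.5. Of 19 tested 12 rose and none fell, 15 and 1 adjusted over the list alone, with Atf3 (log2 3.53 ± 0.74), Fosb (3.39 ± 0.66), Klf4 (3.14 ± 0.32, from 903 ± 232 to 8074 ± 2581) and the inducible heat shock gene Hspa1a (2.86 ± 0.86) first. The list's mean log2 signal was 10.01, 8.67 and 9.09 in E11.5 A, B and C and 12.13, 10.94 and 10.28 in E14.5 A, B and C. Without E14.5 A the change of Atf3 was 2.61 and that of Hspa1a 1.66; without E11.5 B that of Fosb was 2.56, and Hspa1a missed the threshold without E11.5 B or E11.5 C (highest adjusted p 0.0791), with no filter (0.0881) and after quantile normalization (0.0625). Atf3 changed by 2.33 with the higher floor and Hspa1a by 2.06, and without the letter A arrays Hspa1a by 1.95. Without E14.5 C, Atf3 changed by 4.15 and Hspa1a by 3.62, and without E11.5 A, Fosb by 4.02. Of 18 genes of the contractile cytoskeleton and adhesion 7 rose and none fell, 8 and 1 adjusted over the list alone, with the integrin gene Itga1 (2.93 ± 0.43) and the smooth muscle gene Tagln (2.26 ± 0.42) first. Itga1 changed by 1.26 with the higher floor, less than Tagln (1.91). Of 8 genes of MHC class I and interferon response 5 rose, and as many adjusted over the list alone, led by Bst2 (1.83 ± 0.28). Camera called the immediate early (median 2.10, adjusted p = 9.2e-04), contractile (0.51, 0.0184) and MHC lists (1.31, 0.0201). Adjusted p = 0.454 with an estimated correlation for immediate early genes, 0.306 for contractile and 0.418 for MHC genes. Without E14.5 A the contractile (adjusted p = 0.0537) and MHC calls (0.0568) were lost.

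Markers of other cell types also differed. Of 18 tested cartilage markers 10 rose, and as many adjusted over the list alone, with Cytl1 (log2 4.54 ± 0.69), Hapln1 (4.23 ± 0.86), Matn1 (3.49 ± 1.21) and Epyc (3.42 ± 0.69) first. The list's mean log2 signal was 8.27, 7.72 and 8.47 in E11.5 A, B and C and 11.82, 9.60 and 8.44 in E14.5 A, B and C. Sox9, the transcription factor gene of chondrogenesis, was at 2411 ± 211 and 1409 ± 942 (-1.01 ± 0.41, adjusted p = 0.0766), and was called as lower without E14.5 A (-1.52, adjusted p = 0.0040), with the letters as a block (0.0470), after median centring (0.0446), with array weights (0.0217), with the 3' to 5' covariate (0.0451) and without the letter A arrays (0.0188). Without E14.5 A, Cytl1 changed by 3.67, Hapln1 by 3.07 and Epyc by 2.44, and without E14.5 C Cytl1 by 5.42 and Hapln1 by 5.33. Without the letter A arrays Cytl1 changed by 3.51, Hapln1 by 3.15 and Epyc by 2.44. Hapln1 changed by 3.16 with the higher floor and 3.48 with the mean of probe sets, and Epyc by 2.74 with array weights. Matn1 missed the threshold with any 1 array but E14.5 C left out (highest adjusted p 0.143), its change ranging from 1.95 without E14.5 A to 4.87 without E14.5 C. It was also lost with the higher floor (0.0512), no filter (0.135), quantile normalization (0.0731), a trended and robust prior (0.104), array weights (0.0549), the 3' to 5' covariate (0.0569), without the letter A arrays (0.0720) and in a fit of the 6 arrays (0.0779). Camera called the cartilage list (median 2.01, adjusted p = 0.0203; adjusted p = 0.634 with an estimated correlation, and 0.139 by fry), but not without E11.5 B (1.72, 0.0637) or E14.5 A (0.92, 0.112). Of 22 skeletal muscle genes 9 rose, 10 adjusted over the list alone, led by the muscle stem cell gene Pax7 (2.30 ± 0.48) and the contractile protein genes Myl4 (1.87 ± 0.34) and Tnnt2 (1.72 ± 0.27), and the muscle progenitor gene Pax3 fell (-1.58; chosen after its value was seen). Myog, which encodes the muscle differentiation factor myogenin, rose from 703 ± 228 to 1821 ± 291 (1.41 ± 0.27, adjusted p = 0.0029). Of 11 markers of muscle connective tissue and fibroblasts 7 rose, and as many adjusted over the list alone, led by Dpt and Cd34 (5.32 ± 0.23, from 37.2 ± 10.6 to 1439 ± 37.7). Of 16 endothelial markers only 8 passed the signal filter and were tested. Of these 7 rose, and as many adjusted over the list alone, led by the angiopoietin receptor gene Tek (3.24 ± 0.26). Markers with a low signal at every stage are left out by the filter, so such counts hold for the tested members only. Camera called the muscle (median 0.86, adjusted p = 0.0063), fibroblast (2.26, 5.6e-04) and endothelial lists (1.72, 0.0021). Adjusted p = 0.418 with an estimated correlation for muscle, 0.132 for fibroblasts and 0.190 for endothelium. Cd34 changed by 3.99 with the higher floor, Tek by 2.40 and Pax7 by 1.59, and with the mean of probe sets Pax3 by -2.21.

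Of 15 markers of epidermis and limb ectoderm 8 passed the signal filter. Among these 6 rose, led by Perp (log2 2.87 ± 0.23) and the E-cadherin gene Cdh1 (1.57 ± 0.29), and 1 fell, with the same numbers adjusted over the list alone. The 1 that fell was the keratin gene Krt8 (-0.83), chosen after its value was seen and lost without E11.5 B, E11.5 C, E14.5 B or E14.5 C (highest adjusted p 0.0825), with no filter (0.0637) and with a trended and robust prior (0.0521). Camera called the list (median 1.24, adjusted p = 0.0400). Adjusted p = 0.259 with an estimated correlation. The list's call was lost without E11.5 B (0.0608) or E14.5 B (0.0687). Tested were 8 of 15 Schwann cell and neuron markers and 7 of 16 macrophage and leukocyte markers. Among the 8, 4 rose and 2 fell, and among the 7, 3 rose and 1 fell, with the same numbers adjusted over each list alone. Neither list was called by camera (medians 0.76 and 0.86, adjusted p = 0.489 and 0.340), while fry called both (5.0e-04 and 0.0314). The neurofilament gene Nefl (2.80 ± 0.45), the glial gene S100b (2.78 ± 0.42) and the macrophage mannose receptor gene Mrc1 (1.82 ± 0.37) rose, and the neuronal tubulin gene Tubb3 fell (-1.88 ± 0.43). With the higher floor Cdh1 (0.49, adjusted p = 0.0520), Mrc1 (0.33, 0.205) and Tubb3 (-0.48, 0.162) were not called, while Perp changed by 2.01, S100b by 1.43, Alpl by 1.23, Hbb-bh1 by -1.50 and Hba-x by -1.65. With no floor Tubb3 changed by -3.19 and Hbb-bh1 by -4.36. Without the letter A arrays Tubb3 was lost (0.0727), and Alpl changed by 1.47. Too few members for a test were measured of the bone list, of which 2 of 4 rose, Phex (4.37 ± 0.32) and the alkaline phosphatase gene Alpl (2.27 ± 0.40), and of the erythroid list. Of the latter 2 of 3 fell, the embryonic globin genes Hbb-bh1 (-3.44 ± 0.60) and Hba-x (-2.74 ± 0.75). As many were called adjusted over each list alone. The call of Hba-x was lost without E11.5 A, E14.5 A or E14.5 C (highest adjusted p 0.0584), with no filter (0.0655) and without the letter A arrays (-1.55, 0.0841), with a change of -2.05 without E11.5 A and of -3.39 without E14.5 B.

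In all, limma called 4691 of 11575 genes (40.5%) between E11.5 and E14.5, of which 2646 rose and 2045 fell; 1462 rose and 467 fell at least 2-fold. Of the 4691, 4677 changed in the same direction in each of the 3 letters. The genes were called on these same arrays, so this agreement largely follows from the calls and is no separate replication. Where a called gene had several probe sets, all moved in the same direction for 1999 of 2206 genes. After median centring 2308 genes passed. Of the 2000 of these that changed at least 2-fold 57.4% were higher, against 75.8% of 1929 at the authors' scaling, so the size of the excess of 2-fold rises depends on the scaling. After median centring, 5 of the 117 called genes covered by the rule for named genes missed the threshold. With 1 array left out at a time, 104 of the 117 passed in every fit.

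**Figure D3:**
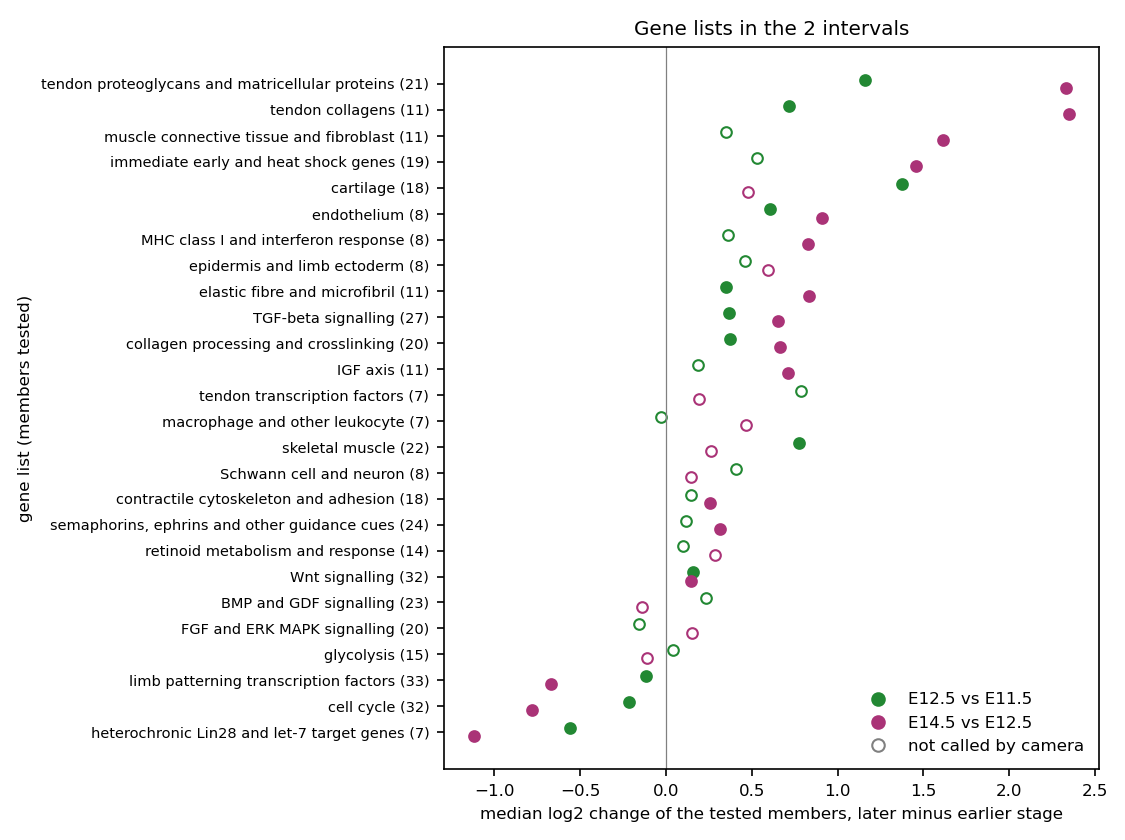
Median log2 change of each of 26 gene lists between E11.5 and E12.5 and between E12.5 and E14.5, with a filled point where camera called the list at its preset correlation and an open point where it did not. Tendon collagens (2.35) and proteoglycans (2.33) have the largest called rises in the second interval and the heterochronic genes the largest called fall (-1.12).

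E12.5 was compared with E11.5, the first interval. Shh fell most, from 1019 ± 193 to 39.1 ± 27.3 (SD, n = 3; log2 -4.74 ± 0.35, adjusted p = 5.6e-04), and Igdcc3 fell from 2479 ± 917 to 360 ± 74.8 (-2.73 ± 0.32, adjusted p = 0.0036). The largest rises were those of Scin, which encodes the actin-severing protein scinderin, from 46.1 ± 19.7 to 383 ± 75.4 (3.15 ± 0.56, adjusted p = 0.0189), Chodl, from 20.7 ± 15.0 to 227 ± 103 (2.94 ± 0.38, adjusted p = 0.0051), the scavenger receptor gene Scara5 (2.86 ± 0.32), the homeobox gene Irx1 (2.72 ± 0.39), the sulfate donor synthesis gene Papss2 (2.67 ± 0.43) and Scrg1 (2.62 ± 0.60). The pro-apoptotic gene Pmaip1 (-2.20 ± 0.45), the glycine decarboxylase gene Gldc (-1.83 ± 0.31), Sall4 (-1.75 ± 0.28) and the Wnt agonist gene Rspo2 (-1.63 ± 0.36) fell next. Scin was not called without E11.5 B, E12.5 B or E12.5 C (highest adjusted p 0.0829), Papss2 without E12.5 B or E12.5 C (0.0573), Gldc without E11.5 B (0.0568) and Sall4 without E12.5 C (0.0528). Pmaip1 was lost without any 1 E11.5 array, E12.5 B, E12.5 C or E14.5 B (0.134). Scrg1 was lost without any 1 of the E11.5 and E12.5 arrays or E14.5 B (0.168) and with the letters as a block (adjusted p = 0.0603), and Rspo2 without E11.5 A, E11.5 B, any E12.5 array, E14.5 B or E14.5 C (0.16). At E11.5, 1 array of Chodl and 2 of Scrg1 lay at the floor, and with the higher floor their changes were 1.19 (adjusted p = 0.117) and 0.91 (0.481) and were not called. Shh then changed by -3.47, Scin by 2.06 and Scara5 by 1.80, all still called, and with no floor Chodl changed by 3.86. With no filter Scin, Irx1, Papss2, Scrg1, Pmaip1, Gldc, Sall4 and Rspo2 were lost (adjusted p from 0.0540 for Irx1 to 0.171 for Scrg1). Quantile normalization ended the calls of Scrg1 (0.0595), Pmaip1 (0.0619) and Rspo2 (0.0600), the mean of probe sets those of Scrg1 (0.0536) and Sall4 (-0.95, 0.0965), the 3' to 5' covariate those of Scrg1 (0.0664) and Rspo2 (0.0539), and a pseudocount that of Scrg1 (0.0692). Without the letter A arrays Gldc (0.0504) and Rspo2 (0.131) were lost, and in a fit of the 6 arrays Rspo2 (0.0747).

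Of the tendon transcription factors only Mkx was called among 7 tested, 2 adjusted over the list alone, from 429 ± 73.4 to 811 ± 118 (log2 0.92 ± 0.19, adjusted p = 0.0357). Scx was at 16656 ± 557 at E12.5 (-0.19 ± 0.22, adjusted p = 0.739), Egr1 at 12637 ± 6541 (1.82 ± 0.83, 0.326) and Tnmd at 107 ± 68.3 (1.63 ± 0.55, 0.173), and none of them was called. Without E12.5 A the change of Tnmd was 2.38 and called (adjusted p = 0.0084). That of Egr1 was 2.94 and called without E11.5 A (0.0228), and 0.97 without E11.5 B. Without the letter A arrays Tnmd (2.67, adjusted p = 0.0076) and Egr1 (2.56, 0.0438) were called. The change of Tnmd was 0.45 with the higher floor and 2.37 with none. Col1a1 was at 1839 ± 173 (0.72 ± 0.18, adjusted p = 0.0678, and 0.0448 without E14.5 A) and Col1a2 at 19914 ± 2566 (0.22 ± 0.17, 0.596). Col1a1 was called with the stricter filter (0.0440), a trended and robust prior (0.0249), array weights (0.0271) and the 3' to 5' covariate (0.0487). The call of Mkx was lost without any 1 E11.5 array, E12.5 B, E12.5 C or E14.5 B (highest adjusted p 0.139), with no filter (0.101), after quantile normalization (0.0504), after median centring (0.314) and in a fit of the 6 arrays (0.0530). The list was not called by camera (median 0.79, adjusted p = 0.0768), but was by fry (0.0319), by camera with the letters as a block (adjusted p = 0.0212) and without E11.5 A (0.0245), E11.5 B (0.0455) or E12.5 C (0.0280).

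Matrix genes had begun to rise. Of 11 tendon collagen genes 5 rose, 7 adjusted over the list alone, among them Col14a1 (log2 1.59 ± 0.26), Col6a3 (1.57 ± 0.23), Col6a1 (1.51 ± 0.22) and Col6a2 (1.37 ± 0.15). Of 21 proteoglycan and matricellular genes 8 rose, 16 adjusted over the list alone, among them Aspn (2.45 ± 0.32), Ogn (2.28 ± 0.28), the decorin gene Dcn (2.26 ± 0.25, from 498 ± 141 to 2363 ± 535) and the keratocan gene Kera (2.18 ± 0.31). Lox (1.48 ± 0.21) and P4ha3 (1.08 ± 0.18) rose among 20 collagen processing genes, 7 adjusted over the list alone, and Efemp1 (1.38 ± 0.23) and Fbln5 (1.18 ± 0.21) among 11 elastic fibre genes, 3 adjusted over the list alone. Camera called the collagens (median 0.72, adjusted p = 4.0e-07), proteoglycans (1.16, 8.2e-11), processing genes (0.37, 6.1e-05) and elastic fibre genes (0.35, 0.0034). Adjusted p = 0.287 with an estimated correlation for collagens, 0.265 for proteoglycans, 0.365 for processing and 0.350 for elastic fibres. Fry did not call the processing genes (0.0579). Aspn was at the floor in all E11.5 arrays, and with the higher floor its change was 0.56 and was not called (adjusted p = 0.324), and with no floor it was 3.72. Col14a1 and Efemp1 missed the threshold without E12.5 B or E12.5 C (highest adjusted p 0.0650 and 0.0719), P4ha3 without these or E11.5 B (0.0768), and Fbln5 without these, E11.5 A or E11.5 C (0.0900). After median centring P4ha3 (0.203) and Fbln5 (0.101) were lost, and after quantile normalization P4ha3 (0.0512). With no filter Col14a1 (0.0669), Kera (0.0505), P4ha3 (0.0574), Efemp1 (0.0668) and Fbln5 (0.0751) were lost, and without the letter A arrays Kera (0.0610), Efemp1 (0.0680) and Fbln5 (0.0656).

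Of 27 TGF-beta signalling genes 7 rose, led by Ltbp3 (log2 1.39 ± 0.17), Inhba (1.25 ± 0.24) and Tgfbr2 (1.22 ± 0.14), and Acvr2b fell (-0.76; chosen after its value was seen), 8 and 1 adjusted over the list alone. Of 32 Wnt signalling genes 5 rose, led by Wnt4 (2.57 ± 0.40), Wnt2 (1.53 ± 0.23) and Dkk2 (1.34 ± 0.20), 10 adjusted over the list alone with 2 that fell. Of 33 limb patterning genes Hoxd13 rose (0.88 ± 0.14) and Sall4 and Irx3 (-1.37 ± 0.18) fell, 1 and 8 adjusted over the list alone. Of 7 heterochronic genes Trim71 fell (-1.32 ± 0.18), 4 adjusted over the list alone. Camera called the TGF-beta (median 0.37, adjusted p = 0.0034), Wnt (0.16, 0.0382), patterning (-0.12, 0.0036) and heterochronic lists (-0.56, 2.6e-06). Adjusted p = 0.344 with an estimated correlation for TGF-beta, 0.287 for Wnt, 0.311 for patterning and 0.265 for heterochronic genes. Fry did not call the patterning list (0.118). The Wnt call was lost with the letters as a block (0.0541) and without E11.5 A (0.0515), E11.5 C (0.0782), E12.5 A (0.0690) or E12.5 C (0.0695). Acvr2b was lost without E11.5 A, E11.5 B, any 1 E12.5 array or E14.5 B (highest adjusted p 0.132). Inhba was lost without E11.5 A, E11.5 B, E12.5 B or E12.5 C (highest adjusted p 0.101), Hoxd13 without E12.5 B or E12.5 C (0.0571) and Sall4 without E12.5 C (0.0528). After median centring Tgfbr2 (0.0596), Acvr2b (0.375) and Hoxd13 (0.414) were lost. With no filter Inhba (0.0920), Acvr2b (0.0748), Wnt4 (0.0665), Sall4 (0.0618) and Aldh1a2 (0.0600) were lost, with the mean of probe sets Acvr2b (0.165), Hoxd13 (0.0688) and Sall4 (-0.95, 0.0965), and in a fit of the 6 arrays Inhba (0.0588) and Acvr2b (0.0677). Without the letter A arrays Acvr2b (0.133) and Trim71 (0.0523) were lost. The retinoid genes Aldh1a3 (2.45 ± 0.23) and Aldh1a2 (1.36 ± 0.22; 0.0604 without E12.5 C), both of retinoic acid synthesis, rose in a list that was not called by camera (adjusted p = 0.319) or fry (0.0657). With the higher floor Wnt2 (0.14, adjusted p = 0.732) and Aldh1a3 (0.55, 0.239) were not called, and Wnt4 changed by 1.65. With the mean of probe sets Wnt4 changed by 1.95, and with no floor Aldh1a3 by 4.01.

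Of 32 cell cycle genes none was called by limma, nor any adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05, while camera called the list as lower (median log2 change -0.22, adjusted p = 2.6e-06; adjusted p = 0.366 with an estimated correlation, and 0.224 by fry). Of 19 immediate early and heat shock genes none was called by limma, nor any adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. The list was not called (median 0.53, adjusted p = 0.0529, and 0.356 by fry). It was called with the letters as a block (adjusted p = 0.0029) and without E11.5 A (7.9e-04), E12.5 C (7.5e-04), E14.5 A (0.0178) or E14.5 C (0.0311). Of 18 cartilage markers none was called by limma, 2 adjusted over the list alone and 7 higher at an unadjusted p under 0.05, and camera called the list as higher (median 1.37, adjusted p = 3.3e-04; adjusted p = 0.453 with an estimated correlation, and 0.214 by fry). Sox9 was at 2845 ± 310 (0.24 ± 0.41, adjusted p = 0.840). Of 22 skeletal muscle genes Myl4 rose (1.46 ± 0.34) and Pax3 fell (-1.60 ± 0.29), 9 and 2 adjusted over the list alone, and Myog was at 934 ± 275 (0.42 ± 0.27, adjusted p = 0.503). Of 8 endothelial markers 1 rose, 2 adjusted over the list alone, the ETS factor gene Erg (1.65 ± 0.30). Camera called the muscle (median 0.78, adjusted p = 0.0022) and endothelial lists (0.61, 0.0137). Adjusted p = 0.365 with an estimated correlation for muscle and 0.344 for endothelium, and 0.0865 and 0.0579 by fry. The muscle call was lost without E12.5 A (0.0632) and the endothelial call without that array (0.0632), E11.5 A (0.0515) or E11.5 B (0.0507). Myl4 was lost with any 1 array but E11.5 C left out (highest adjusted p 0.163) and with the letters as a block (adjusted p = 0.0678), Pax3 without E11.5 B, E11.5 C, E12.5 B or E12.5 C (0.0927) and Erg without E12.5 B or E12.5 C (0.0968). With no filter Myl4 (0.161), Pax3 (0.0888) and Erg (0.0973) were lost, and in a fit of the 6 arrays Myl4 (0.100) and Erg (0.0554). Myl4 was also lost with no floor (0.0558), quantile normalization (0.0597), the mean of probe sets (0.0547), array weights (0.0507), the 3' to 5' covariate (0.0678) and without the letter A arrays (0.85, 0.142). Of 7 macrophage markers none was called by limma, nor any adjusted over the list alone or at an unadjusted p under 0.05. They had a median of -0.03, a mean of 0.09 and a downward test that missed the threshold (adjusted p = 0.945, and 0.638 by fry).

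In this interval limma called 411 genes (3.55%), of which 360 rose and 51 fell, and 224 rose and 23 fell at least 2-fold. All 411 changed in the same direction in each letter, which again largely follows from their being called on these arrays. Where a called gene had several probe sets, all had the same direction of change between the stages for 139 of 145 genes. The count varied with the array left out, which also leaves fewer samples. It was 210 without E11.5 A, 210 without E11.5 B, 133 without E12.5 B, 125 without E12.5 C, 267 without E14.5 B and 486 without E14.5 A. After median centring it was 175. Of 54 called genes covered by the rule for named genes, 23 passed with each array left out in turn.

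E14.5 was compared with E12.5, the second interval. Tnmd rose most, from 107 ± 68.3 to 8066 ± 1811 (SD, n = 3; log2 6.52 ± 0.55, adjusted p = 8.5e-05), and by 5.78 without E12.5 A. Dpt rose from 36.4 ± 13.1 to 2116 ± 404 (5.89 ± 0.28, adjusted p = 4.7e-06), and Ecrg4 (5.58 ± 0.47), the matricellular gene Ccn3 (5.48 ± 0.37), Aspn (5.08 ± 0.32, adjusted p = 2.0e-05) and C1qtnf3 (4.82 ± 0.61, and 5.61 without E12.5 B) followed. Calb2, which encodes the calcium-binding protein calretinin, fell most, from 546 ± 330 to 42.1 ± 49.8 (-3.72 ± 0.64, adjusted p = 0.0036, and -4.43 without E14.5 A), before Arid3b (-3.11 ± 0.21), Zic5 (-2.88 ± 0.32), the connexin gene Gja3 (-2.62 ± 0.26), Fbxo41 (-2.56 ± 0.31) and Trim71 (-2.56 ± 0.18). With the higher floor these 6 were still called, in another order: Calb2 changed by -2.39, Zic5 by -2.15, Trim71 by -2.13, Gja3 by -1.20, Arid3b by -1.13 and Fbxo41 by -0.90. The rises were then 4.69 for Ecrg4, 4.53 for Dpt, 4.14 for C1qtnf3 and 3.98 for Ccn3, below Tnmd and Aspn. Without the letter A arrays Tnmd changed by 5.65, Ecrg4 by 4.66 and C1qtnf3 by 4.14, and with no floor Arid3b by -4.57. Mkx rose further (1.09 ± 0.19, adjusted p = 0.0043, and 0.0514 after median centring, where it was not called), the only tendon transcription factor of 7 tested to be called, also adjusted over the list alone, and the list was not called by camera (adjusted p = 0.842) or fry (0.585). Scx (-0.62 ± 0.22, adjusted p = 0.0750, and 0.0214 without E14.5 C, 0.0332 with a trended and robust prior, 0.0445 with array weights and 0.0497 with the 3' to 5' covariate) and Egr1 (0.83 ± 0.83, 0.506) were not called.

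Of the tendon matrix, 11 of 11 collagen genes, 18 of 21 proteoglycan and matricellular genes, 11 of 20 processing genes and 9 of 11 elastic fibre genes rose and none fell, with 11, 21, 15 and 10 adjusted over each list alone. Col1a1 rose from 1839 ± 173 to 11983 ± 2278 (log2 2.69 ± 0.18, adjusted p = 2.8e-05), Col14a1 by 3.57 ± 0.26, Postn by 4.08 ± 0.56, the thrombospondin gene Thbs4 by 3.79 ± 0.31, Lox by 2.89 ± 0.21 and Mfap5 by 3.97 ± 0.32. Col1a2 rose by 0.67 ± 0.17 (adjusted p = 0.0223), a call lost without E12.5 A, E12.5 B or E14.5 C (highest adjusted p 0.0782), after median centring (0.349) and without the letter A arrays (0.105). Mfap5 changed by 3.29 with the higher floor. Camera called the collagens (median 2.35, adjusted p = 1.2e-11), proteoglycans (2.33, 1.7e-15), processing genes (0.66, 3.6e-08) and elastic fibre genes (0.84, 1.5e-06). Adjusted p = 0.0892 with an estimated correlation for collagens and for proteoglycans, 0.223 for processing and 0.114 for elastic fibres.

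Of 27 TGF-beta signalling genes 14 rose, led by Ltbp2 (log2 3.70 ± 0.48), and 3 fell, 14 and 4 adjusted over the list alone. The 3 were Acvr2b (-1.54), Tgif1 (-1.13) and Tgfbr1 (-0.52), chosen after their values were seen. Tgfbr1 was lost without E12.5 B or E14.5 C (highest adjusted p 0.0681), after median centring (0.301) and without the letter A arrays (0.106), and with the higher floor Ltbp2 changed by 2.21. Of 32 Wnt genes 10 rose, with Sfrp4 (2.18 ± 0.53) and Dkk3 (2.09 ± 0.30) first, and 2 fell, 11 and 2 adjusted over the list alone. The 2 were Frzb (-1.64) and Lef1 (-0.80), also chosen after their values were seen. Lef1 was lost without E11.5 A, any 1 E12.5 array, E14.5 A or E14.5 C (highest adjusted p 0.134), with no filter (0.105), after median centring (0.154), with array weights (0.0627) and without the letter A arrays (0.199). Sfrp4 was lost without E12.5 A, E12.5 B or E14.5 C (highest adjusted p 0.0568), with no filter (0.0656) and without the letter A arrays (0.0822). Of 11 IGF axis genes 6 rose, and as many adjusted over the list alone, with Igfbp7 (2.70 ± 0.40), Igfbp6 (2.19 ± 0.49) and Igf1 (2.16 ± 0.13) first. Igfbp6 was lost with no filter (0.0535) and without the letter A arrays (0.109), and changed by 1.42 with the higher floor. Of 24 guidance cues 8 rose, with Sema3e (1.76 ± 0.28) first, and 1 fell, 9 and 1 adjusted over the list alone. That was Nrp2 (-0.63), chosen after its value was seen and lost without E12.5 C or E14.5 C (highest adjusted p 0.0588), after median centring (0.192), with the mean of probe sets (0.157) and without the letter A arrays (0.127). Of 33 limb patterning genes 16 fell and none rose, 20 and 2 adjusted over the list alone, led by Sall4 (-2.04 ± 0.28, and -0.90 with the higher floor) and Lhx9 (-1.94 ± 0.28). Of 7 heterochronic genes 6 fell, and as many adjusted over the list alone, with Mycn (-1.51 ± 0.23) after Trim71, and of 32 cell cycle genes 22 fell, 28 adjusted over the list alone, led by Aurka (-1.29 ± 0.21) and Plk1 (-1.18 ± 0.18). Camera called the TGF-beta (median 0.65, adjusted p = 0.0033), Wnt (0.15, 0.0189), IGF (0.71, 7.1e-04), guidance (0.31, 0.0110), patterning (-0.67, 3.5e-06), heterochronic (-1.12, 1.6e-05) and cell cycle lists (-0.78, 1.2e-11). Adjusted p = 0.267 with an estimated correlation for TGF-beta, 0.104 for Wnt, 0.0892 for IGF, 0.297 for guidance, 0.0892 for patterning, 0.104 for heterochronic genes and 0.267 for the cell cycle. In the retinoid list, which was not called by camera (adjusted p = 0.753) or fry (0.830), 4 of 14 rose and 4 fell, also adjusted over the list alone, and Aldh1a2 fell by 1.80 ± 0.22 from 1718 ± 176 to 505 ± 144.

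Of 19 immediate early and heat shock genes 2 rose, and as many adjusted over the list alone, Klf4 (log2 2.02 ± 0.32) and Hspb1 (1.23 ± 0.25), and of 8 MHC class I and interferon genes 4 rose, 5 adjusted over the list alone, led by Bst2 (1.70 ± 0.28). Of 18 contractile and adhesion genes 4 rose, and as many adjusted over the list alone, led by Itga1 (2.34 ± 0.43, and 1.26 with the higher floor). Of 11 fibroblast markers 5 rose, 7 adjusted over the list alone, with Cd34 (3.72 ± 0.23) after Dpt and Mfap5, and of 8 endothelial markers 2 rose, 3 adjusted over the list alone, Tek (2.31 ± 0.26) and Ramp2 (1.17 ± 0.19). Camera called the immediate early (median 1.46, adjusted p = 0.0012), MHC (0.83, 0.0077), contractile (0.25, 0.0201), fibroblast (1.62, 1.9e-05) and endothelial lists (0.91, 0.0114). Adjusted p = 0.469 with an estimated correlation for immediate early genes, 0.308 for MHC, 0.297 for contractile genes, 0.0892 for fibroblasts and 0.267 for endothelium. Fry did not call the immediate early list (0.132). The contractile call was lost without E12.5 C (0.0518) or E14.5 A (0.0741). After median centring Hspb1 (0.0570) and Ramp2 (0.0532) were lost.

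The cartilage list was not called between E12.5 and E14.5 (2 of 18 rose and none fell, 0 adjusted over the list alone in limma, with 3 higher and 2 lower at an unadjusted p under 0.05; median log2 change 0.48, adjusted p = 0.617, and 0.828 by fry), and its direction rested on single arrays. Without E14.5 A it was called as lower (-0.69, adjusted p = 0.0428), and without E14.5 C as higher (1.21, 0.0133). Cytl1 (2.32 ± 0.69) and Col11a1 (1.31 ± 0.38) rose. Cytl1 was lost without E11.5 A, E11.5 B, E14.5 A, E14.5 B or any 1 E12.5 array (highest adjusted p 0.104; change 1.45 without E14.5 A and 3.20 without E14.5 C), and Col11a1 without E11.5 A, E14.5 B or any 1 E12.5 array (0.120) and with the letters as a block (0.0501) or after median centring (0.0585). Both were lost with no filter (0.118 and 0.109), without the letter A arrays (Col11a1 0.140) and in a fit of the 6 arrays (0.0665 and 0.0637), and Cytl1 with a trended and robust prior (0.0709) and the 3' to 5' covariate (0.0502). Sox9 went from 2845 ± 310 to 1409 ± 942 (-1.24 ± 0.41, adjusted p = 0.0559) and was called as lower with the letters as a block (adjusted p = 0.0353) and without E14.5 A (-1.76, 0.0049). It was also called with a pseudocount (0.0464), the higher floor (0.0403), the stricter filter (0.0369), median centring (0.0483), array weights (0.0125), the 3' to 5' covariate (0.0339) and without the letter A arrays (0.0268). Skeletal muscle genes were not called as a list (4 of 22 rose, also adjusted over the list alone; median 0.26, adjusted p = 0.164, and 0.337 by fry), except without E12.5 A (0.29, 0.0094). Pax7 (2.20 ± 0.48, 1.51 without E12.5 C and 1.52 with the higher floor; lost without the letter A arrays, 0.0552) and Tnnt2 (1.33 ± 0.27) rose, and Myog (0.99 ± 0.27, adjusted p = 0.0285) was lost without E12.5 B, E12.5 C or any 1 E14.5 array (0.0948), with no filter (0.0782) and after median centring (0.194).

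**Figure D4:**
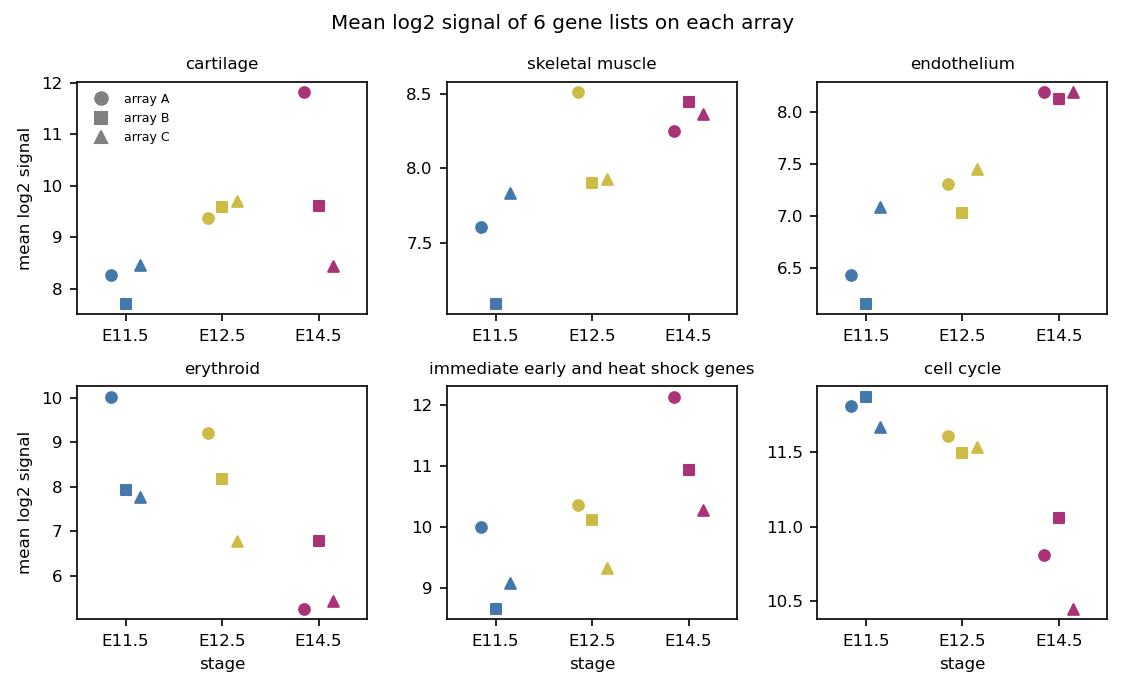
Mean log2 signal of the tested members of 6 gene lists in each array, against stage, with 1 point per array marked by its letter. Cartilage markers spread most at E14.5, from 8.44 in array C to 11.82 in array A, and immediate early genes are highest in array A at every stage.

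Between E12.5 and E14.5 limma called 2542 genes (22%), of which 1463 rose and 1079 fell, and 763 rose and 219 fell at least 2-fold. All 2542 changed in the same direction in each letter, which again largely follows from their being called on these arrays. Where a called gene had several probe sets, all had the same direction of change between the stages for 1082 of 1162 genes. The count was 1564 without E12.5 A and 860 after median centring. Of the 2-fold changes 69.3% of 854 were higher after centring, against 77.7% of 982. Of the 100 called genes covered by the rule for named genes, 81 passed with each array left out in turn.

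Over the 3 stages together, limma's F-test found a difference in 3904 of 11575 genes (33.7%). Of the genes called in both intervals, 240 rose in both and 24 fell in both, while 18 turned. Col6a1 and Lox were among those that rose in both. If the calls in the intervals were independent, 45.5 genes would rise in both and 4.75 would fall in both. The intervals share the E12.5 arrays, which pushes chance errors of the intervals in opposite directions: among equally many top-ranked genes of simulated data with no change, means of 4.10 and 3.87 genes moved the same way and of 118 and 116 opposite ways. The 264 genes that moved the same way in both intervals numbered 131 without E11.5 A, 150 without E11.5 B, 159 without E12.5 A, 82 without E12.5 B, 80 without E12.5 C, 171 without E14.5 B and 97 after median centring.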

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

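The setting without the arrays of letter A was chosen after seeing the data; all others were planned. A threshold of at least 2-fold left 1929 genes between E11.5 and E14.5 (1462 higher and 467 lower), 247 between E11.5 and E12.5 (224 and 23), 982 between E12.5 and E14.5 (763 and 219) and 1908 in the test of any difference. Median centring moved the median log2 change of all genes to -0.20, -0.04 and -0.16 in these comparisons, and small changes are to be read against that shift; it left 2308 (1248 and 1060), 175 (155 and 20) and 860 genes (597 and 263), 1710 in the test of any difference and 97 genes moving the same way in both intervals, and the cause of the lower counts was not tested. Of the genes called at the authors' scaling, 2220 of 4691, 152 of 411 and 827 of 2542 were still called. Between E11.5 and E12.5, no filter gave 182 genes (154 and 28) of 18193 tested, and every probe set tested alone 189 (170 and 19) of 24370, both with more tests to adjust for; quantile normalization left 33 lower genes and array weights gave 79, and the cause was not tested. Genes moving the same way in both intervals numbered 114 with no filter and 405 with array weights. Without letter A, which leaves fewer samples, 1260 genes were lower at E14.5 than at E11.5, 249 were called between E11.5 and E12.5 (225 and 24), 1084 between E12.5 and E14.5 (785 and 299), 2280 in the test of any difference and 140 moved the same way in both intervals; the cartilage list was then lower at E14.5 than at E12.5 (median -0.83), as it was without E14.5 A alone (-0.69), and higher without E14.5 C (1.21). Leaving out 1 array at a time gave 3855 to 4535 genes between E11.5 and E14.5 (2306 to 2576 higher, 1536 to 1959 lower), 125 to 486 between E11.5 and E12.5 (113 to 423 and 12 to 63), 1564 to 2599 between E12.5 and E14.5 (1010 to 1502 and 554 to 1097), 3034 to 3614 in the test of any difference, 46 to 49 called pairs of list and contrast, and 80 to 270 genes moving the same way in both intervals. With the letters as a replicate block, 5262 genes (2895 and 2367), 527 (454 and 73) and 3091 (1717 and 1374) were called, with 4438 in the test of any difference, 48 list and contrast pairs and 339 genes moving the same way in both intervals. The block also called Sox9 between E11.5 and E14.5 (adjusted p = 0.0470) and not Eya2 (0.0521), and beyond these and the changes given beside the results it changed no call of a named gene or list. Camera called 47 of 78 list and contrast pairs at its preset correlation, and fry called 49. Camera with an estimated correlation called 0, with 20 at an unadjusted p under 0.05. Across settings other than leaving out 1 array, the list results kept their direction and side of the threshold 890 times, passed it anew 41 times, missed it 67 times and turned 1 time. For the genes covered by the rule these numbers were 3627, 22, 237 and 0. Of the 67 lost list calls, 47 were with the estimated correlation, 8 with fry and 3 without letter A. Quantile normalization, the higher floor and array weights each ended 2, and no filter, the stricter filter and the block 1 each. With 1 array left out at a time they were 667, 16, 18 and 1 for lists and 2290, 6, 242 and 0 for genes. Signals near the background limit the precision of the largest changes: that of Tnmd between E11.5 and E14.5 was 6.45 with a higher floor and 8.88 with none, that of Aspn 5.54 and 8.80.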

Other observations

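The genes named here outside the rule were chosen after their values were seen, and the second stress, cartilage, muscle and neural lists were written after the pattern that each tests and before their own values were seen. Irf1 of the second stress list is an exception, as it also belongs to the MHC class I and interferon list.

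Few genes turned at E12.5. Of those called in both intervals, 12 rose and then fell, where 33.6 would be found if the intervals were independent, and 6 fell and then rose, where 6.45 would be found. Aldh1a2, a retinoic acid synthesis gene, went from a mean signal of 673 to 1718 and then 505 (log2 1.36 ± 0.22 and -1.80 ± 0.22, SE, n = 3 per stage), and Hoxd13, a patterning gene of the distal limb, from 5491 to 10076 and then 5357 (0.88 ± 0.14 and -0.91 ± 0.14). Rspo2, which encodes a Wnt agonist, went from 795 to 233 and then 611 (-1.63 ± 0.36 and 1.36 ± 0.36). In the first interval the call of Aldh1a2 was lost without E12.5 C (adjusted p = 0.0604), that of Hoxd13 without E12.5 B or E12.5 C (highest 0.0571) and that of Rspo2 without E11.5 A, E11.5 B, any 1 E12.5 array, E14.5 B or E14.5 C (highest 0.16). In the second interval Rspo2 was lost without any 1 E12.5 array or E14.5 B (highest 0.0792). With no filter the first-interval calls of Aldh1a2 (0.0600) and Rspo2 (0.145) and the second of Rspo2 (0.0791) were lost, as were the first of Hoxd13 (0.414) and the second of Rspo2 (0.0524) after median centring. The mean of probe sets ended that of Hoxd13 (0.0688), and quantile normalization (0.0600), the 3' to 5' covariate (0.0539) and a fit of the 6 arrays (0.0747) the first of Rspo2, which was lost in both intervals without the letter A arrays (0.131 and 0.0992). The same E12.5 arrays enter both intervals, so their chance errors favour such turns.

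The lists of Schwann cell and neuron markers and of epidermal markers were not called by camera between E12.5 and E14.5, although single members rose. Of 8 Schwann cell and neuron markers 2 rose and 3 fell, 3 and 3 adjusted over the list alone (adjusted p = 0.948, and 0.828 by fry). S100b, a glial gene, rose from 20.3, with 2 of 3 arrays at the floor, to 253 ± 148 (log2 3.02 ± 0.42, adjusted p = 0.0012, and 1.43, 0.0155, with the higher floor), and Nefl by 1.74, while Tubb3 (-2.25), Isl1 (-1.36) and Erbb3 (-0.72) fell. Nefl was lost without E12.5 A, E12.5 C, E14.5 B or E14.5 C (highest adjusted p 0.0726), Isl1 without E12.5 B or E12.5 C (0.0616), Erbb3 without E12.5 A or E14.5 C (0.0584) and Tubb3 with the higher floor (0.126). With no filter Nefl (0.0768) and Isl1 (0.0664) were lost, after median centring Erbb3 (0.156), and without the letter A arrays Tubb3 (0.0741) and Erbb3 (0.0653), where S100b changed by 2.43. Of 8 epidermal markers 3 rose and none fell, and as many adjusted over the list alone, Perp (1.75 ± 0.23), Cdh1 (1.72 ± 0.29) and Krt5 (1.31 ± 0.27), and fry called the list (0.0101) where camera did not (0.0748); Cdh1 was lost with the higher floor (0.0756) and Krt5 without the letter A arrays (0.0712). Of 4 bone markers, too few for a test, 2 rose, Phex (2.64 ± 0.32) and Alpl (2.17 ± 0.40, and 1.23 with the higher floor), also adjusted over the list alone. Of 20 genes of FGF and ERK signalling 5 rose and 1 fell in that interval, and the same adjusted over the list alone, with the growth factor gene Fgf7 (1.75 ± 0.24) and the receptor gene Fgfr4 (1.33 ± 0.29) first. Fgfr4 was lost with the mean of probe sets (0.77, 0.147) and without the letter A arrays (0.0635). The ERK phosphatase gene Dusp6 fell (-1.14 ± 0.27), a call lost without E12.5 A (adjusted p = 0.0598), with no filter (0.0539) and without the letter A arrays (0.0632), and the list was called by fry (0.0108) and not by camera (0.135).

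The 9 arrays can be grouped in other ways. For each pair of stages, 10 splits of the 6 arrays exist, too few for a share under 0.05, and in each case only the real split, 1 of 10, gave as many genes or lists. The real splits gave 4691, 411 and 2542 genes, against 0 as the highest of the other splits. The real splits gave 19, 12 and 16 lists, where the other splits gave 5 to 15, 0 to 9 and 7 to 13. Camera at its preset correlation thus called lists in most groups that mix the stages. A list call on its own is therefore weak evidence of a change with stage. For a difference among the 3 stages, 100 of 280 partitions were drawn. Only the real grouping, 1 of the 100, gave as many genes, 3904 against a highest other of 2726. That share is under 0.05, but it is the smallest that 100 draws can give. The partitions also took no account of the letters, so chance is unlikely but not excluded.

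Immediate early and heat shock genes were higher at E14.5 than at E11.5 (median log2 change 2.10), a list that camera called at its preset correlation and not at an estimated one (adjusted p = 0.454). The list's mean was highest in array A at every stage, and without the arrays of letter A its median change was 1.95. Neither a single array nor the scaling accounts for it: the lowest median with 1 array left out was 1.37, and the median was 1.99 after quantile normalization. A second list of 24 stress-induced genes had a median of 1.01, with 9 that rose, among them Cebpb (2.81 ± 0.34), while the chaperone gene Hsph1 fell (-1.12 ± 0.25). The median was just above the value set beforehand for a stress response to dissociation and sorting that was larger in the E14.5 samples. Irf1 (1.48) is also in the MHC class I and interferon list. Without Irf1 the median is the change of Bag3 (0.94), below that value. The same holds if any other single gene above the median is left out, so the second list cannot decide this explanation. A difference in these genes between the stages in the embryo stays open and was not tested. Egr1, read as a tendon regulator, belongs to the same genes, so its rise may have either source.

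Camera called cartilage and skeletal muscle markers as higher at E14.5 than at E11.5, in cells that a sort for Scx-GFP should have parted from most muscle, and neither list with an estimated correlation (adjusted p = 0.634 and 0.418). The cartilage call between E11.5 and E14.5 rests on single arrays. It was lost without E11.5 B (0.0637) or E14.5 A (median 0.92, adjusted p = 0.112) and was not made by fry (0.139). The list's mean log2 signal was 11.82, 9.60 and 8.44 in E14.5 A, B and C. The last is within the range of the E11.5 arrays, 7.72 to 8.47. The E14.5 samples thus differed among themselves, which a change with stage alone would not give, and why was not tested. At E12.5 the list's mean was 9.38 to 9.71, above every E11.5 array. All 18 tested members were then higher than at E11.5 (median 1.37), though limma called none of them and fry did not call the list (0.214). A second cartilage list, of which 11 genes were tested, had a median log2 change of 0.82, with 10 genes higher and 5 that rose. A second muscle list, of which 21 were tested, had a median of 0.46, with 15 higher, 6 that rose and 2 that fell. Neither median reached the value set beforehand for a larger share of these cells, and neither fell below the value set against it, so a larger share of cartilage or of muscle cells cannot be told apart from a change within the sorted cells. All of these genes were measured in the sorted cells, some of which may express cartilage genes themselves. A change with stage in the reporter-positive cells stays open and was not tested.

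Zic2, Zic5, Rfx4 and Tubb3, genes of the neural tube or of neurons, were lower at E14.5 than at E12.5 (log2 -2.29, -2.88, -2.29 and -2.25). With the higher floor Rfx4 (-0.32, adjusted p = 0.0894) and Tubb3 (-0.58, 0.126) were not called and Zic5 changed by -2.15, and without the letter A arrays Tubb3 was not called (0.0741). In a list of other neural genes, of which 11 were tested, the median change was -0.21, with 3 that rose and 3 that fell. A candidate explanation is a few neural cells at the earlier stages. The median lay above -0.25, the value set beforehand as speaking against this explanation. It did so by less than its spread over the genes (SD over the square root of their number, 0.26), an allowance not part of the value set beforehand. The list's members also went both ways, so neural cells cannot be told apart from a change in the limb cells. A change of these genes with stage in the limb stays open and was not tested.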
